A study of Mus musculus with 16 samples.

How the data were processed

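Total RNA of thymocytes with (ESET+/+) and without (ESET-/-) ESET, sorted from C57BL/6 mice, was measured on Illumina expression BeadChips. A deposited list of the RNA samples names the +/+ samples w/w and the -/- samples F/F. Per the labels, RNA was isolated with an RNeasy kit and labelled with biotin using a TargetAmp-Nano kit. The 16 arrays were placed in groups by their titles: preselection double-positive cells (preDP, 4 arrays per genotype), postselection double-positive cells (postDP, 1 array per genotype) and CD4 single-positive cells (CD4SP, 3 arrays per genotype). The labels do not say that the samples of a group came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

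Per the file headers, the gene profile table holds for every probe and array the mean signal of its beads, an intensity from which the array background has been subtracted and which is not normalized between arrays. The deposited table also gives the detection p-value of each probe, the share of negative control beads at or above its signal, and the standard error and number of its beads. The deposited non-normalized table holds the same signals and served only for that comparison. The series table holds log2 values normalized by the authors. The authors' method is not given in the sources used here. In that table every probe is centred on its median over the 16 arrays. Array medians lie between -0.00397 and 0.00517, and differences between arrays follow differences of the log2 signals with a slope of 0.971 to 1.02 and a correlation across probes of at least 0.996.

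Of 25697 lines of the gene profile table, 103 were empty as received and 25594 probes were used. Probe names were updated with a RefSeq table (assembly GRCm38.p6), which matched 97.4% of the probes and gave 17870 gene symbols, 5029 of them with more than 1 probe. Between 11089 and 12102 probes per array had a detection p-value under 0.05, which is 43.3% to 47.3% of the probes. The median number of beads per probe was 39 on preDP 01 of both genotypes and 40 on the other arrays. Signals near the level of the negative control beads set the lowest expression that could be told from none, and the number of arrays limits the precision.

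Signals of all 16 arrays were corrected for background, given an offset of 16 and quantile normalized together with the neqc function of limma 3.58.1 in R 4.3.3. The level of the negative probes was taken from the detection p-values. Probes with a detection p-value under 0.05 on at least 3 of the 14 replicated arrays were kept (13234 probes), and the probe with the highest mean stood for each of 9755 genes. A limma model with 1 mean per group was fitted to the 14 arrays of preDP and CD4SP, with moderated variances (10 residual and 6.61 prior degrees of freedom). Contrasts were -/- against +/+ in preDP, the same in CD4SP, the difference between these effects (interaction), and CD4SP against preDP in each genotype. The p-values were adjusted by Benjamini and Hochberg over the 9755 genes with a threshold of 0.05. Differences are log2 values of -/- minus +/+ with the standard error (SE) of the model. Where no array of 1 group detected a gene, its fold was computed against the detection limit and is given as a lower bound. Where 1 array of a replicated group detected it, no fold is given. The 2 postDP arrays entered no test.

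The model, the threshold, the gene lists, the naming rule and the first group of alternative settings were fixed before the data were examined. Genes named are the 10 largest rises and 10 largest falls past the threshold with no overlap between the groups' arrays, for preDP and CD4SP. To these come the 5 largest interaction values each way, the 10 largest changes each way with maturation in +/+, the 10 largest postDP differences each way, and always Setdb1 and Fcgr2b. Of each list, up to 4 members with the largest differences past the threshold are named, or up to 2 where none passed. Model names and clone names are counted but not named. Some genes that this rule names are not reported here. Iap, Amigo2, Fam110b and Gpr183 were named after their values were seen.

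The 24 lists were H3K9 methylation and heterochromatin machinery, Fc receptors and inhibitory receptors, TCR signalling components, TCR-induced and positive selection genes, ERK pathway regulators, CD4 lineage genes, CD8 lineage and cytotoxic genes, preselection DP genes, mature single-positive genes, early thymic progenitor and double-negative (DN) genes, regulatory T cell genes and effector T helper genes. They also were gamma-delta and innate-like T cell genes, markers of NK cells, B cells, myeloid and dendritic cells, thymic stroma and erythroid cells, germline genes, interferon-stimulated genes, p53 targets and apoptosis genes, cell cycle genes, housekeeping genes, and endogenous retrovirus-related transcripts found by keyword. Lists were tested with camera of limma against all other genes, with a correlation between genes preset to 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. For postDP, the median of each list was set against 10000 random lists of the same size matched on mean expression. Such ranks set genes against genes on 1 pair of arrays and do not test a difference between the genotypes.

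Alternatives tried were an offset of 50, no background correction with signals floored at 1, median scaling, the authors' normalized values, no filter and a stricter filter on dim probes (detection p-value under 0.01 on every array of a group). Further ones were the mean of a gene's probes, only the arrays compared, a variance trend with robust estimates, array weights, the replicate number as a block, each array left out in turn, and a fold minimum of 2. The negative control signal added back, each probe tested on its own, preDP 01 and 03 averaged, preDP 03 of both genotypes left out and CD4SP 03 of both genotypes left out were chosen after seeing the data. The deposited list of the RNA samples gives the arrays preDP 01 and preDP 03 of a genotype the same RNA name, preDP 01, in both genotypes. This is why the last settings on preDP were added. The list names the RNA of both preDP 04 arrays preDP 03 (replaced), so array and RNA numbers differ for preDP 03 and 04. The spread between 01 and 03 was 1.37 times the bead noise in variance in +/+, the lowest of all pairs of arrays of a group. In -/- it was 1.85, and that of 01 and 04 was 1.38. Whether 01 and 03 are repeats of 1 RNA therefore stays open. The model has no block. The labels do not say what the replicate numbers mark, but in CD4SP the deviations of equal numbers from the group means correlated between the genotypes with 0.432, 0.211 and 0.492, each over 0.1, so CD4SP values with the block are given where they change a call.

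The fit and camera were tested on simulated values with the spread of these arrays. Changes were added after normalization and filtering, so background correction, normalization and the filter were not tested. Simulated falls of dim genes were not limited by the background as real ones are, so recovery of such falls is overstated. The fit called 64.2%, 95.5% and 100% of genes changed by a log2 of 0.5, 1 and 2 in preDP. In CD4SP it called 53.7%, 95.5% and 100%. Of unchanged genes, 0.0733% (preDP) and 0.0523% (CD4SP) were called. Camera called the simulated list of 15 genes raised by 0.3 and 0 of 40 unchanged lists. The simulated genes varied independently of one another, so camera was not tested on lists with correlated members. The estimated correlation was 0.67 in the cell cycle list and 0.37 in the NK list. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.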

Results

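RNA levels were measured in 16 thymocyte samples, 8 labelled ESET+/+ and 8 labelled ESET-/-. ESET, also called Setdb1, is an enzyme that methylates histone H3 at lysine 9, a mark of silent chromatin. Preselection double-positive cells (preDP) are CD4+CD8+ thymocytes that have not yet passed positive selection, postselection double-positive cells (postDP) have received that signal, and CD4 single-positive cells (CD4SP) are the mature stage of the helper lineage. Probes detected per array numbered 11358 to 11773 in +/+ preDP, 11089 to 11677 in -/- preDP, 11383 to 12102 in +/+ CD4SP, 11191 to 11885 in -/- CD4SP, and 11761 (+/+) and 11825 (-/-) in postDP, of 25594 probes. The comparisons ask what changes in thymocytes without ESET at each stage, whether the changes are shared between stages, and how the normal change with maturation proceeds without ESET.

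In preDP cells, more genes rose than fell without ESET, and several rose from near the detection limit. The largest rise was in Fcrla, an Fc receptor-like gene of B cells (log2 difference 4.25 ± 0.22 SE, 19.0-fold, adjusted p = 4.80e-09). It was followed by Stag3, a cohesin subunit of meiotic chromosomes (3.49 ± 0.16, 11.2-fold), Il18r1, a chain of the interleukin-18 receptor (2.82 ± 0.19, 7.08-fold), and Fcgr2b, the inhibitory Fc receptor for IgG. Fcgr2b, fixed in advance as a gene of interest, was detected on 4 of 4 -/- and 0 of 4 +/+ arrays and rose by 2.63 ± 0.26, at least 5.46-fold (adjusted p = 4.80e-06). Its other probes differed by 1.03 and 0.27. Further rises were in the potassium-chloride cotransporter Slc12a7 (5.03-fold), the RNA export gene Alyref2 (4.31-fold), the cilium gene Rsph1 (4.08-fold), the pregnancy-specific glycoprotein Psg23 (3.81-fold), Fbxo27 (3.36-fold) and Trim80 (at least 2.96-fold).

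Large falls in -/- preDP cells were in Ly6d (-2.05 ± 0.30, 4.13-fold, adjusted p = 0.000507) and the potassium channel Kcnh3 (2.93-fold). The cystine transporter Slc7a11 (2.84-fold), Bex2 (2.32-fold), Wdr78 (2.28-fold), Ppm1e (2.12-fold), Scara3 (2.10-fold) and Emid1 (2.03-fold) fell as well. The signal of Setdb1 itself was 1.64-fold lower, at a mean of 6.62 (SD 0.18, n = 4) against 7.34 (SD 0.06, n = 4) in log2 (difference -0.72 ± 0.11, limma adjusted p = 0.00067). The array holds 1 probe for Setdb1 that was used, and its place relative to the deleted part of the gene is not known. Of 9755 genes tested, 141 were higher and 87 lower in -/- (2.34%), of which 41 and 10 by at least 2-fold. At an unadjusted p under 0.05 there were 1071 genes.

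Among interferon-stimulated genes, 6 of 28 measured fell in -/- preDP and 0 rose (10 lower when adjusted over the list alone), including Ifi27l2a (-0.95), the RNA sensor regulator Dhx58 (-0.70), Ly6a (-0.61) and Ifi27 (-0.59). The list had a median of -0.19 (camera adjusted p = 6.94e-07, adjusted p = 0.243 with an estimated correlation). The 6 calls became 3 without +/+ preDP 03 or without -/- preDP 03, and 0 with preDP 01 and 03 averaged or with preDP 03 of both genotypes left out. With the average, in which fewer samples remain, the values were -0.77 ± 0.20 (Ifi27l2a), -0.63 ± 0.16 (Dhx58), -0.58 ± 0.17 (Ly6a) and -0.56 ± 0.14 (Ifi27), somewhat smaller and with the same sign. Of 10 CD4 lineage genes, the costimulatory receptor Icos fell (-0.80, adjusted p = 0.00353; 4 lower when adjusted over the list alone), with a list median of -0.26 (adjusted p = 0.00153, adjusted p = 0.208 with an estimated correlation). Of 14 genes of H3K9 methylation and heterochromatin machinery, Atf7ip, which encodes a partner protein of Setdb1, rose by 1.20 and Morc3 by 0.44 while Setdb1 fell (median -0.02, mean 0.04, camera adjusted p = 0.731). Of 19 mature single-positive genes, the tetraspanin Cd53 (1.08) and the integrin chain Itgb7 (0.83) rose and Slfn2 fell (-0.49; 2 higher and 3 lower when adjusted over the list alone, adjusted p = 0.415).

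In 9 other lists 1 or 2 members passed in preDP. Fcrla was the 1 riser of 8 B cell markers (adjusted p = 0.0716), Il18r1 the 1 riser of 12 effector T helper genes (2 when adjusted over the list alone, adjusted p = 0.0642), and Fcgr2b the 1 riser of 10 Fc receptors and inhibitory receptors (1 higher and 1 lower when adjusted over the list alone). Among 27 TCR signalling components 1 gene rose and 1 fell, the latter Rasgrp1, an activator of Ras (-0.38, but -0.15 with adjusted p = 0.754 with the mean of its probes). Cd53 rose and the transcriptional inhibitor Id3 fell (-0.54) among 20 TCR-induced and positive selection genes, whose median was -0.01 and mean 0.04. The phosphatase Dusp4 fell (-0.72) among 17 ERK pathway regulators, and Ly6d was the 1 of 14 preselection DP genes that fell. The interleukin-2 receptor chain Il2ra rose (0.73) and is in the list of 13 early thymic progenitor and DN genes as well as that of 10 regulatory T cell genes, whose median was -0.01 and mean 0.12. In these lists the counts adjusted over the list alone were the same except where given, and camera gave adjusted p-values of at least 0.415 in the lists for which no other is stated.

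In 11 lists, 0 genes passed in preDP by limma. They were CD8 lineage and cytotoxic genes (14 measured; Tbx21 -0.19, Prf1 -0.19), NK cell markers (13; Prf1 -0.19, Fcer1g 0.18), cell cycle genes (22; Pcna -0.36, Mcm7 -0.29), endogenous retrovirus-related transcripts (5; Tax1bp3 -0.30, Tax1bp1 -0.18) and erythroid markers (3; Gata1 0.15, Klf1 -0.15). The others were gamma-delta and innate-like T cell genes (5; Cd163l1 0.32, Klrb1f 0.18), germline genes (6; Xlr5c -0.32, Zfp42 0.17), housekeeping genes (10; Actb -0.14), myeloid and dendritic cell markers (17; Siglech -0.27, H2-Aa -0.24), p53 targets and apoptosis genes (20; Bax 0.29, Ccng1 0.27) and thymic stroma markers (4; Krt8 -0.16, Ccl25 -0.13). At an unadjusted p under 0.05 the count was 1 each for the cell cycle, retrovirus-related, germline and p53 lists and 0 for the others. Adjusted over the list alone, 1 retrovirus-related gene was lower. The retrovirus-related genes measured are cellular genes that a keyword picked, so this list does not measure retroviral transcripts. Of the 13 NK cell markers, 10 were detected on at most 1 of 4 +/+ preDP arrays, so a fall could not be measured in them. Camera gave adjusted p-values of at least 0.415 in each of the 11 lists, and the cell cycle list had a median of 0.03 and a mean of -0.02. The sign turned for Actb with the mean of its probes (0.03), for Mcm7 without -/- preDP 03 (0.06) or with preDP 03 of both genotypes left out (0.12), and for Prf1 without +/+ preDP 02 (0.16) or without -/- preDP 03 (0.07).

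The count of lower genes in preDP went from 87 to 57 without +/+ preDP 03, to 43 with preDP 01 and 03 averaged, to 41 with preDP 03 of both genotypes left out, and to 49 with the authors' normalized values, and it rose to 129 with array weights. With the authors' values Ly6d, Slc7a11, Ppm1e, Scara3, Rasgrp1, Id3, Il2ra, Slfn2, Ly6a and Ifi27 no longer passed. Their values were at least as large, as in Ly6d (-2.12 ± 0.69), Slc7a11 (-1.61 ± 0.57) and Scara3 (-1.54 ± 0.53), where the SE grew. Without +/+ preDP 03 alone, Rasgrp1, Morc3, Id3, Il2ra, Slfn2, Ly6a and Ifi27 no longer passed, and with an offset of 50 neither did Icos (-0.43, adjusted p = 0.0606), Dusp4 (-0.37, adjusted p = 0.0554), Il2ra (0.40, adjusted p = 0.1) and Ly6a (-0.46, adjusted p = 0.0565). With the negative control signal added back, Icos (-0.30), Dusp4 (-0.25), Il2ra (0.28), Dhx58 (-0.35), Ly6a (-0.38) and Slfn2 (-0.19) had smaller values and did not pass.

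**Figure D1:**
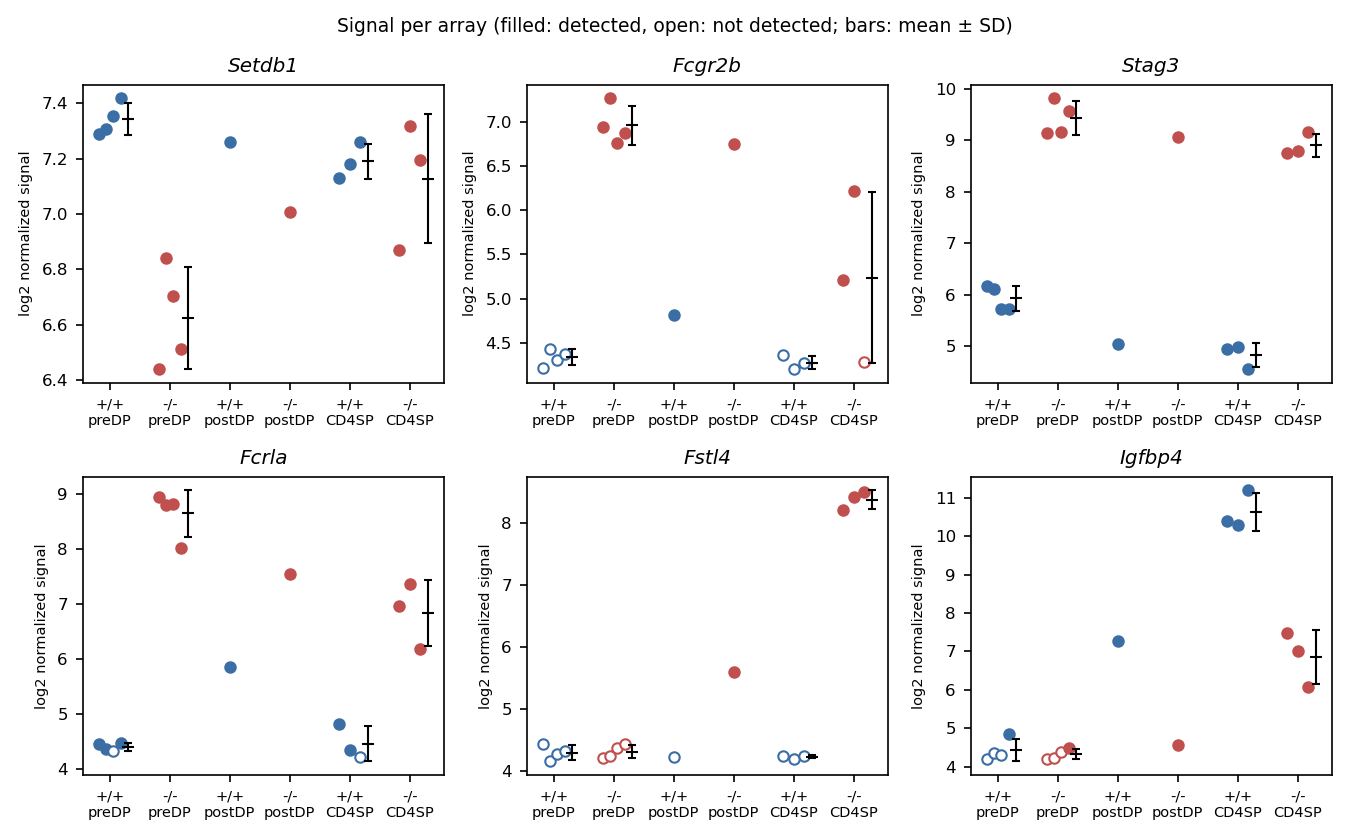
Log2 value of 6 genes on each of the 16 arrays by group; filled points are arrays on which the gene was detected, open points arrays on which it was not, and bars show the mean ± SD of each replicated group. Fcgr2b lies at a mean of 6.96 in -/- preDP against 4.33 in +/+ preDP, and Igfbp4 at 6.85 in -/- CD4SP against 10.63 in +/+ CD4SP.

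In CD4SP cells, loss of ESET raised Fstl4, a secreted follistatin-like gene, which was not detected on any +/+ array (4.16 ± 0.11, at least 14.7-fold, adjusted p = 1.14e-13). It also raised Stag3 (4.07 ± 0.19, 16.8-fold), the transcriptional cofactor Cited4 (3.90 ± 0.14, 15.0-fold) and the laminin-binding integrin chain Itgb4 (3.38 ± 0.14, 10.4-fold). Psg23 (6.18-fold), Fcrla (5.19-fold), Snai3 (4.63-fold), Tnfrsf22, a decoy receptor for the death ligand TRAIL (3.85-fold), the epithelial transcription factor Grhl2 (at least 3.83-fold) and Akr1c12 (3.65-fold) followed. The largest falls were in Igfbp4, an IGF-binding protein (-3.78 ± 0.28, 13.8-fold, adjusted p = 1.84e-07), and in Klra16 of the Ly49 receptor family (7.40-fold). The cytokine Il4 (-2.68 ± 0.25, 6.42-fold), the receptor gene Gpr83 (-2.38 ± 0.14, 5.21-fold) and Klrd1, which encodes CD94 (-2.15 ± 0.24, 4.43-fold) fell too. Further falls were in Klra10 (at least 3.30-fold), Dhdh (3.01-fold), Nrn1 (-1.51, detected on 1 of 3 -/- arrays), Klra7 (at least 2.73-fold) and Klrb1c, which encodes the NK1.1 antigen (at least 2.48-fold). Probes for the Klra genes may read related members of the family.

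The Setdb1 signal differed by -0.06 ± 0.13 in CD4SP (adjusted p = 0.919), and by 0.07 without -/- CD4SP 01. Its values were 6.87, 7.32 and 7.20 on the -/- arrays against 7.13, 7.18 and 7.26 on the +/+ arrays. Fcgr2b differed by 0.96 ± 0.30 (at least 1.67-fold) and did not pass the adjustment (adjusted p = 0.106), with detection on 2 of 3 -/- and 0 of 3 +/+ arrays. With the replicate numbers of CD4SP as a block, its adjusted p was 0.0396, and without -/- CD4SP 03, on which it was not detected, the difference was 1.44 (adjusted p = 0.000686). Without -/- CD4SP 02 it was 0.47, and with array weights 1.19 (adjusted p = 0.0225). The lysozyme gene Lyz1, of the myeloid list, was also lowest on -/- CD4SP 03. It had 8.38, 7.75 and 4.97 on -/- CD4SP 01, 02 and 03, where Fcgr2b was 5.21, 6.22 and 4.29. Between 01 and 02 the 2 genes went in opposite directions. Of 9755 genes, 162 were higher and 160 lower in -/- CD4SP (3.30%), of which 54 and 31 by at least 2-fold, and 1272 had an unadjusted p under 0.05.

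Of 13 NK cell markers measured, 8 fell in -/- CD4SP and 0 rose (1 higher and 8 lower when adjusted over the list alone). They were the receptor genes Klrd1, Klra7, Klrb1c, Klra1 (-1.50), Klre1 (-1.08) and Klrk1 (-0.56), the transcription factor Eomes (-1.11) and the chemokine Xcl1 (-0.61). The median was -0.61 (camera adjusted p = 2.92e-10, adjusted p = 0.0954 with an estimated correlation). The remaining members differed by 0.57 (Nkg7), 0.57 (Tyrobp), 0.23 (Fcer1g), -0.34 (Il2rb) and -0.07 (Prf1), and without -/- CD4SP 03 there were 3 risers beside the 8 that fell. Of 14 CD8 lineage and cytotoxic genes, which share members with the NK list, 6 fell and 0 rose (1 higher and 8 lower when adjusted over the list alone). They included the integrin chain Itgae (-1.22) and the transcription factor Tbx21 (-0.88), with a median of -0.51 (adjusted p = 2.08e-07, adjusted p = 0.154 with an estimated correlation). Of 12 effector T helper genes, 4 fell (4 when adjusted over the list alone): Il4, the chemokine receptors Cxcr3 (-1.31) and Ccr8 (-1.13), and Tbx21 (median -0.17, adjusted p = 0.000195, adjusted p = 0.0724 with an estimated correlation). Of 5 gamma-delta and innate-like T cell genes, Klrb1c fell (2 when adjusted over the list alone and 2 with the replicate block; median -0.40, adjusted p = 0.00489, adjusted p = 0.154 with an estimated correlation).

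Myeloid and dendritic cell markers had a median of 0.50 in CD4SP, with 0 of 17 past the limma threshold, 4 at an unadjusted p under 0.05, and the largest values in Lyz1 (1.26) and Siglech (0.84). Their camera adjusted p was 0.0015 (adjusted p = 0.587 with an estimated correlation). With the replicate block 7 of the 17 rose, among them Lyz1 (adjusted p = 0.00167) and Siglech (adjusted p = 0.0263), with CD4SP 03 of both genotypes left out 6 rose, and without -/- CD4SP 03 alone 11 rose. Tyrobp and Fcer1g are in this list as well as in that of NK cells. B cell markers included 2 risers of 8, Fcrla (2.37) and the kinase Btk (0.42; 3 when adjusted over the list alone; adjusted p = 0.0032, adjusted p = 0.0724 with an estimated correlation). The cell cycle list of 22 had a median of -0.31 with 0 genes past the threshold and 3 at an unadjusted p under 0.05 (adjusted p = 0.000872, adjusted p = 0.587 with an estimated correlation). Kif11 (-0.54) and Nusap1 (-0.50) had its largest values, and 2 genes fell with the replicate block, among them Nusap1 (adjusted p = 0.0411), and 2 without -/- CD4SP 01.

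Among 10 regulatory T cell genes in CD4SP, Gpr83 and the transcription factor Foxp3 (-0.57) fell and Tnfrsf9 rose (0.75; adjusted p = 0.344). Atf7ip (1.66), Mbd1 (1.32) and Morc3 (0.63) rose among 14 genes of H3K9 methylation and heterochromatin machinery, whose median was -0.03 and mean 0.21 (adjusted p = 0.0678). Icos fell (-1.25) among 10 CD4 lineage genes (adjusted p = 0.0203, adjusted p = 0.154 with an estimated correlation). The inhibitors Id2 (-0.84) and Id3 (-0.72) fell among 20 TCR-induced and positive selection genes, whose median was 0.03 while mean and test were negative (adjusted p = 0.258). Hhex fell (-1.36; 2 lower when adjusted over the list alone) among 13 early thymic progenitor and DN genes, whose median of 0.21 and test were positive (adjusted p = 0.436). Oas1g fell (-0.76) among 28 interferon-stimulated genes (median -0.08, adjusted p = 0.0377, adjusted p = 0.587 with an estimated correlation). Slfn2 fell (-0.78) among 19 mature single-positive genes (median -0.16, adjusted p = 0.0678; 2 fell with the replicate block). Spo11, which cuts DNA in meiosis, rose (1.06) among 14 preselection DP genes (adjusted p = 0.399), and with the replicate block 2 rose and 2 fell. The protease Asprv1 rose (0.61) among 5 retrovirus-related transcripts, which are cellular genes that a keyword picked (adjusted p = 0.0181, adjusted p = 0.154 with an estimated correlation). Adjusted over the list alone, the counts in this paragraph were the same except for Hhex.

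The other 8 lists had 0 genes past the limma threshold in CD4SP. They were Fc receptors and inhibitory receptors (10; Fcgr2b 0.96, Cd160 -0.54), TCR signalling components (27; Cd8b1 -0.46), ERK pathway regulators (17; Spred1 0.36, Dusp7 -0.20) and germline genes (6; Xlr4a 0.32, Zfp42 0.28). After them came housekeeping genes (10; Gapdh -0.35), p53 targets and apoptosis genes (20; Zmat3 0.31, Pmaip1 0.28), and erythroid (3; Hba-a1 0.30, Gata1 0.11) with thymic stroma markers (4; Ccl25 0.26, Krt8 0.11). At an unadjusted p under 0.05 the counts were 2, 2, 1, 1, 2, 2, 0 and 0 in that order. Camera gave adjusted p-values of at least 0.399 in each of the 8 lists. Adjusted over the list alone, 1 Fc receptor or inhibitory receptor gene was higher and 1 lower, and with the replicate block Fcgr2b, Cd160 (adjusted p = 0.024) and Cd8b1 (adjusted p = 0.0177) passed.

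With the replicate block, the CD4SP counts were 297 higher and 270 lower. With the authors' normalized values they were 111 higher and 77 lower (59.0% higher, against 50.3%), with 5 NK cell markers, 2 CD8 lineage genes and 1 effector T helper gene lower, and Klrd1, Eomes, Tbx21, Cxcr3, Ccr8, Id2, Tnfrsf9, Foxp3 and Btk no longer passed, although each kept its direction with a value at least as large and a larger SE. With the mean of its probes Foxp3 did not pass either (-0.38, adjusted p = 0.0767). The calls of Btk and Foxp3 each ended without 5 of the 6 CD4SP arrays taken singly (adjusted p up to 0.116 and 0.187), and that of Id3 without -/- CD4SP 02 (adjusted p = 0.0553).

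**Figure D2:**
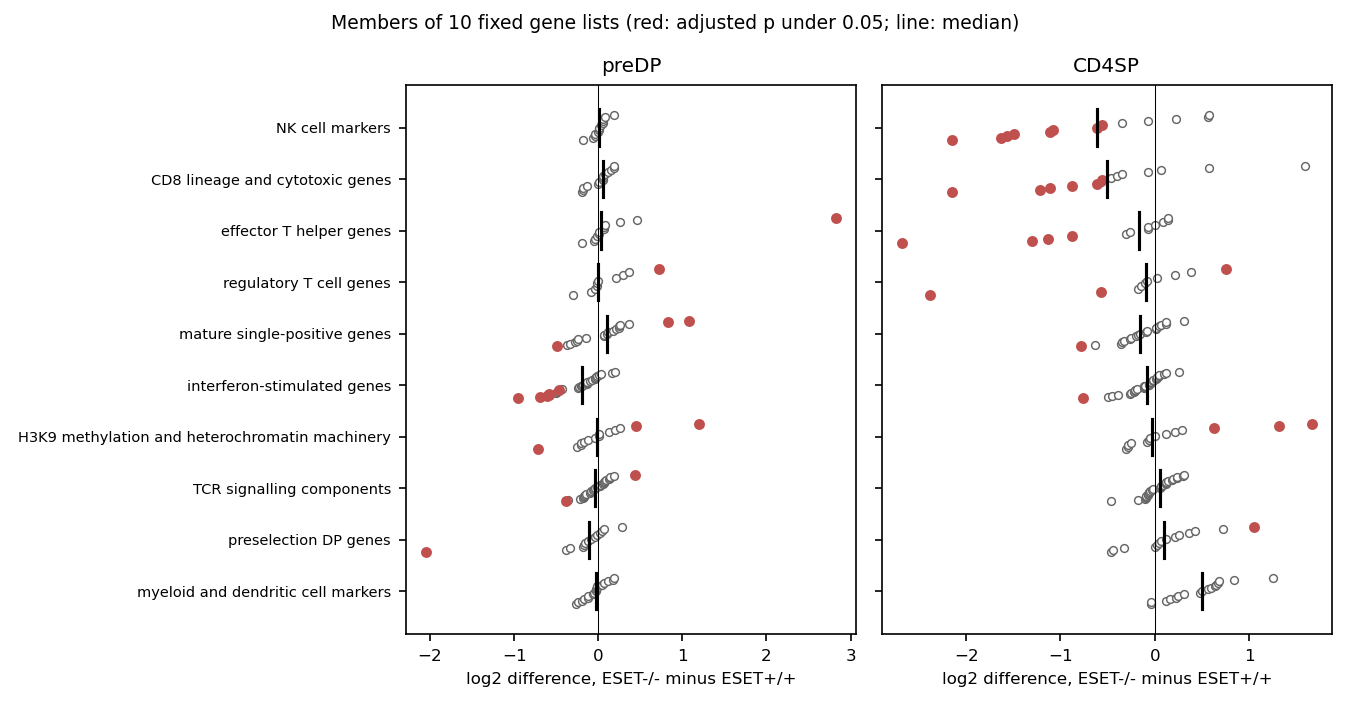
Log2 difference of -/- minus +/+ for each measured member of 10 of the gene lists, in preDP (left) and CD4SP (right); red points passed an adjusted p of 0.05, grey points did not, and the line marks the list's median. The NK cell markers have a median of -0.61 in CD4SP, and the interferon-stimulated genes one of -0.19 in preDP.

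Part of the response was shared between the stages. Of the raised genes, 42 were higher in -/- at both stages against 2.34 for independent lists (Fisher's exact test, p = 2.46e-42). Of the lowered genes, 14 were lower at both against 1.43 (Fisher's exact test, p = 1.11e-10). This test takes genes as independent, and both contrasts share 1 estimate of the spread per gene. Its expected counts and p-values are therefore only a rough guide. The shared rises, given as preDP and CD4SP values, included Stag3 (3.49 and 4.07), Fcrla (4.25 and 2.37), Psg23 (1.93 and 2.63) and Slc12a7 (2.33 and 1.75). They also included Alyref2 (2.11 and 1.22), Tnfrsf22 (1.55 and 1.95), Akr1c12 (1.40 and 1.87), Atf7ip (1.20 and 1.66), Snai3 (1.14 and 2.21) and Grhl2 (0.64 and 2.23). The shared falls included Bex2 (-1.22 and -1.07), Dhdh (-0.81 and -1.59), Icos (-0.80 and -1.25), Slfn2 (-0.49 and -0.78), Oas1g (-0.59 and -0.76) and Id3 (-0.54 and -0.72). In 3 genes the calls were opposite: Amigo2 (0.99 and -0.73), Gpr183 (0.55 and -0.78) and Fam110b (-0.60 and 0.55). With an offset of 50, which shrinks differences of dim genes, none of the 3 passed in preDP (0.47, 0.23 and -0.33; adjusted p = 0.0596, 0.23 and 0.0537 in that order). With the authors' normalized values none passed in CD4SP (adjusted p = 0.281, 0.529 and 0.182), where the values were as large (-0.76 ± 0.28, -0.82 ± 0.43 and 0.68 ± 0.21) and the SE larger. In CD4SP Fam110b also lost its call without 4 of the 6 arrays taken singly (adjusted p up to 0.213) and Amigo2 without -/- CD4SP 01 (0.0726) or +/+ CD4SP 03 (0.0685), and in preDP Fam110b without -/- preDP 04 (0.0537). Of the 228 genes called in preDP, 191 had the same sign in CD4SP, and of the 322 called in CD4SP, 241 had the same sign in preDP. Across all genes, which are not independent replicates, the differences correlated with r = 0.305 (Spearman's rho 0.184). With the replicate block 69 genes were higher and 29 lower at both stages, and with preDP 03 of both genotypes left out 7 were lower at both.

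**Figure D3:**
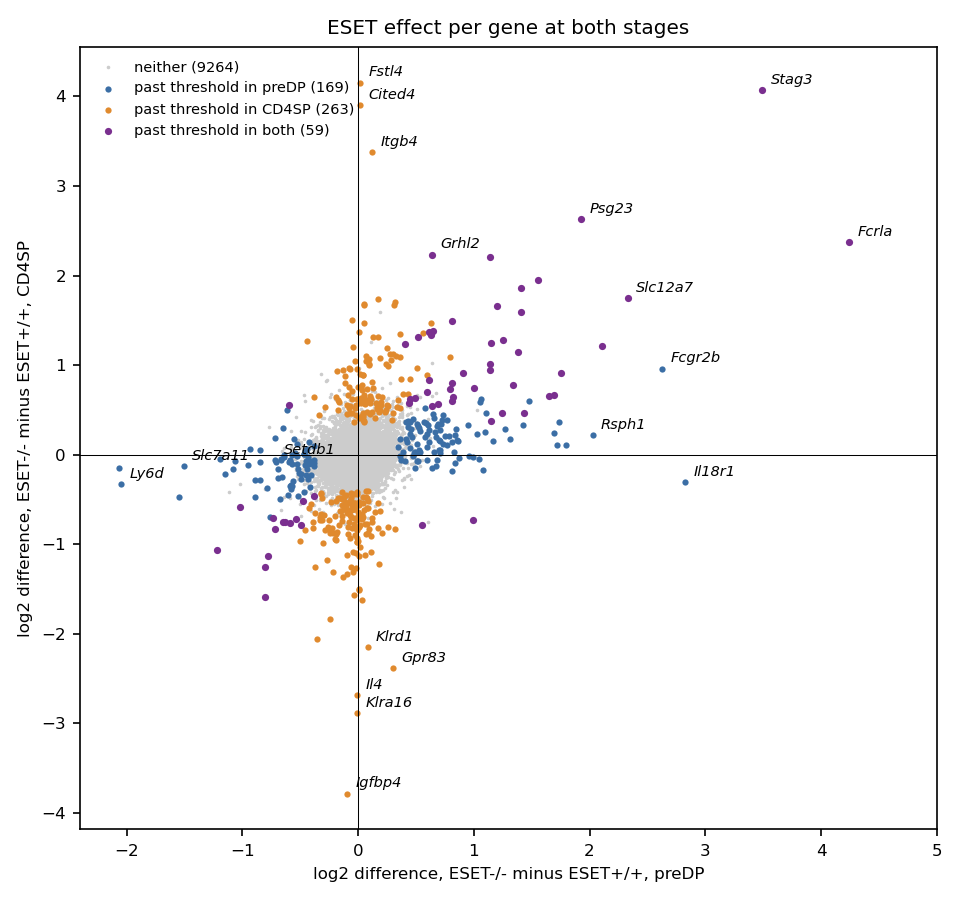
Log2 difference of -/- minus +/+ in CD4SP (vertical) against that in preDP (horizontal) for each of the 9755 genes; colours mark 169 genes called in preDP alone, 263 in CD4SP alone and 59 in both, and 9264 in neither. Stag3 and Fcrla lie high at both stages, and Fstl4, Cited4 and Itgb4 lie high in CD4SP with values near 0 in preDP.

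The effect of ESET loss differed between the stages in 161 genes by the interaction test, with a more positive effect in CD4SP in 73 and a more negative one in 88 (949 at an unadjusted p under 0.05). Fstl4 (4.14 ± 0.14, adjusted p = 1.18e-11), Cited4 (3.89 ± 0.18) and Itgb4 (3.26 ± 0.18) rose far more in CD4SP, and Acoxl rose by 1.27 in CD4SP (interaction 1.71 ± 0.20). On the other side were Igfbp4 (-3.69 ± 0.37), Il18r1 (-3.13 ± 0.29), which differed by -0.30 in CD4SP, Klra16 (-2.88 ± 0.28), Gpr83 (-2.68 ± 0.18) and Il4 (-2.67 ± 0.32). Igfbp4, Klra16 and Il4 were near background in +/+ preDP (detected on 1, 1 and 0 of 4 arrays), where a fall could not be measured, so their interaction restates the CD4SP fall. This holds for 34 of the 56 negative interaction genes that fell in CD4SP, which were detected on at most 1 of 4 +/+ preDP arrays, and for 5 of the 6 NK cell markers among them. The interaction was -1.66 ± 0.40 for Fcgr2b (adjusted p = 0.0412) and 0.65 ± 0.17 for Setdb1 (adjusted p = 0.0641). Of the 161 genes, 36 were called in preDP alone, 103 in CD4SP alone, 15 in both and 7 in neither, and 30 of the 42 genes raised at both stages had no interaction past the threshold. Among the lists, effector T helper genes had 4 negative calls (adjusted p = 1.11e-08, adjusted p = 0.0105 with an estimated correlation), NK cell markers 6 (adjusted p = 4.20e-10, adjusted p = 0.149 with an estimated correlation) and CD8 lineage genes 3 (adjusted p = 4.41e-07, adjusted p = 0.152 with an estimated correlation). Of these calls, 3 of the 4 effector T helper genes and 2 of the 3 CD8 lineage genes were detected on at most 1 of 4 +/+ preDP arrays, and the other effector T helper gene, Il18r1, owes its sign to its preDP rise. The tests of these lists therefore mostly restate the CD4SP falls and that rise. Further lists passed camera only with the preset correlation. Positive were myeloid and dendritic markers (adjusted p = 0.00371), retrovirus-related transcripts (0.00427) and preselection DP genes (0.0358). Negative were gamma-delta and innate-like T cell (0.000986), cell cycle (0.00546) and mature single-positive genes (0.00633). With an estimated correlation their camera adjusted p was at least 0.152. With the authors' normalized values 40 genes passed. Cited4 (5.05 ± 1.00), Igfbp4 (-3.56 ± 1.20), Il18r1 (-5.04 ± 1.01), Klra16 (-4.50 ± 0.91) and Il4 (-4.14 ± 1.18) did not, with a larger SE and values as large or nearly so. With the replicate block 278 passed, and with preDP 03 of both genotypes left out 104.

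Between preDP and CD4SP in +/+ cells about as many genes rose as fell. The interleukin-7 receptor gene Il7r (78.3-fold), the receptor Gpr18 (at least 77.9-fold) and the cyclin Ccnd2 (65.2-fold) were among the largest rises. Igfbp4, detected on 1 of 4 +/+ preDP arrays, rose by a log2 of 6.21, for which no fold is given. Sema4a (49.1-fold), Ctsw (45.5-fold), Gpr83 (44.8-fold), Slfn1 (43.6-fold), Cd53 (42.8-fold) and the transcription factor Klf2, which drives exit from the thymus (39.4-fold), followed. Endou (34.4-fold), Arpp21 (22.9-fold), the recombinase gene Rag1 (22.8-fold) and Ly6d (21.3-fold) were among the largest falls. Slc7a11, detected on 1 of 3 +/+ CD4SP arrays, differed by -4.43 in log2. Without +/+ CD4SP 03 the log2 differences went from -5.10 to -4.44 in Endou, from -4.52 to -3.38 in Arpp21, from -4.51 to -3.58 in Rag1 and from -4.02 to -3.35 in Dntt, and without +/+ CD4SP 01 Arpp21 had -5.20. The DNA polymerase Dntt (16.2-fold), Aqp11 (16.1-fold), Chrna9 (12.8-fold) and Sytl3 (12.7-fold) followed. Of the lists, 17 of 19 mature single-positive genes (adjusted p = 0.00359 with an estimated correlation), 25 of 28 interferon-stimulated genes (adjusted p = 0.0357 with an estimated correlation) and 15 of 20 TCR-induced genes (adjusted p = 0.0357 with an estimated correlation) rose. Conversely, 13 of 14 preselection DP genes (adjusted p = 0.147 with an estimated correlation) and 22 of 22 cell cycle genes fell (adjusted p = 0.149 with an estimated correlation). Of the NK cell markers, 11 of 13 rose in +/+ and 6 of 13 in -/-. In all, 4914 genes changed in +/+ (2398 higher and 2516 lower) and 4778 in -/- (2432 and 2346), of which 1420 and 1355 by at least 2-fold. The stages also differ in the biotin control of the arrays, which was 5408 to 6011 in preDP and 3560 to 4423 in CD4SP. The postDP arrays had 3075 (+/+) and 3346 (-/-), under every CD4SP array, yet lay between the stages along the change with maturation, so this control does not order the arrays as that change does. Array batches are not given in the sources used here, and a part of the change that comes from them is not excluded.

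Along the 1420 genes that changed at least 2-fold with maturation in +/+, where the mean of +/+ preDP is 0 and that of +/+ CD4SP is 1, the -/- preDP arrays lay at 0.0211 to 0.0450 and the +/+ preDP arrays at -0.0126 to 0.0148. The CD4SP arrays 01, 02 and 03 lay at 0.952, 0.992 and 1.06 in +/+ and at 0.883, 0.949 and 1.03 in -/-. Each -/- CD4SP array thus lay lower than the +/+ array of its number. Some genes that fell in -/- CD4SP rise with maturation in +/+, such as Igfbp4 (log2 6.21), Gpr83 (5.49) and Klrd1 (3.13). Other large risers, such as Gpr18 (6.45), Sema4a (5.62) and Ctsw (5.51), differed in -/- CD4SP by -0.22, 0.26 and 0.07. What part a difference in maturation has in the CD4SP falls was not tested. The single postDP arrays lay at 0.673 (+/+) and 0.520 (-/-).

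**Figure D4:**
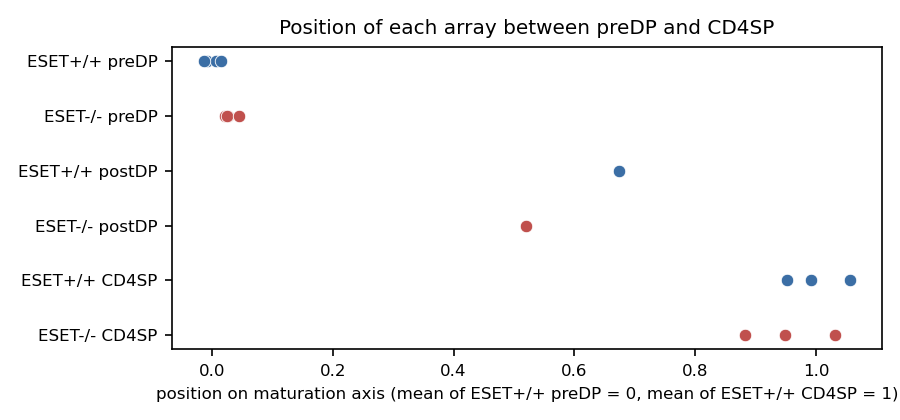
Position of each of the 16 arrays along the change from +/+ preDP (mean 0) to +/+ CD4SP (mean 1) over 1420 genes, by group. The -/- postDP array lies at 0.520 and the +/+ postDP array at 0.673.

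In postDP cells there was 1 array per genotype and therefore no test. Of 8943 genes detected on at least 1 of the arrays, 81 were at least 2-fold higher and 67 at least 2-fold lower in -/-. These counts depend on the treatment of low signals: they were 43 and 26 with an offset of 50, 533 and 519 without background correction, and 530 and 515 with the authors' normalized values. Stag3 (16.1-fold), Cited4 (8.77-fold), Psg23 (7.93-fold), Fbxo27 (6.03-fold), Tle6 (5.12-fold), the tight junction gene Cldn4 (5.08-fold), Pomgnt2 (5.07-fold), the integrin chain Itga3 (4.55-fold) and the keratin Krt10 (4.46-fold) were highest. Igfbp4 (6.58-fold), Gpr83 (4.06-fold), H2-K2 (3.74-fold), Arsb (3.46-fold), Ccnd2 (3.39-fold), Klrd1 (3.18-fold), Nt5e (3.14-fold), Samhd1 (3.00-fold), Ahnak (at least 2.65-fold) and Snurf (at least 2.39-fold) were lowest. Fcgr2b differed by 1.93 and Setdb1 by -0.25. The medians of CD8 lineage and cytotoxic genes (-0.68), NK cell markers (-0.47), interferon-stimulated genes (-0.37) and mature single-positive genes (-0.29) lay below all 10000 random lists, and that of preselection DP genes (0.40) above all of them. H3K9 methylation and heterochromatin machinery had a median of 0.22 (percentile 99.7), TCR-induced genes one of -0.25 (percentile 0.02) and regulatory T cell genes one of -0.21 (percentile 2.92). These ranks hold for 1 pair of arrays and test no difference between genotypes. The lists named here change with maturation, along which the -/- postDP array lay lower than the +/+ one. From preDP to CD4SP in +/+, 12 of 14 CD8 lineage, 11 of 13 NK and 25 of 28 interferon-stimulated genes rose. So did 17 of 19 mature single-positive, 15 of 20 TCR-induced and 9 of 10 regulatory T cell genes. Conversely, 13 of 14 preselection DP genes and 7 of 14 heterochromatin genes fell (2 of the latter rose). The postDP medians of these lists cannot be told apart from a difference in maturation. Of the lowest genes named, all but Snurf rise with maturation in +/+ (log2 from 1.91 in Ahnak to 6.21 in Igfbp4). Of the highest, Cldn4 (-2.58), Tle6 (-2.09) and Pomgnt2 (-1.87) fall the most. A part that maturation has in their postDP differences cannot be told apart either. Cldn4, Tle6 and Pomgnt2 were also higher in -/- preDP (1.11, 1.72 and 1.06). Of the genes called in preDP and in CD4SP, 195 of 228 and 264 of 322 had the same sign in postDP.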

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

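The tests on undeleted cells, on the place of the Setdb1 probe and on a smaller share of NK receptor-bearing cells were chosen after the results they measure were seen, and the others were written before.

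Regrouping the arrays tested whether the counts could arise by chance. In preDP the real grouping gave 228 genes and the highest of the other splits 2. As 1 of 35 splits gave as many, chance is argued against if the 4 arrays per genotype are separate samples. This is the smallest share that 35 splits can give, and it was not adjusted over the comparisons. The RNA list gives preDP 01 and 03 the same name, and 3 samples per genotype would make only 10 splits, too few for a share under 0.05. In CD4SP the 10 splits are too few for a share under 0.05: the real value was 322, reached by 1 split, and the highest other was 44. Among the 4 CD4SP splits that part every pair of equal replicate numbers, the highest other was 0. For the change with maturation, 1 of 35 splits gave as many as the 4914 genes in +/+ (highest other 2880). In -/-, 1 of 35 gave as many as the 4778 (highest other 2748). Chance is argued against here under the same condition and with the same limit. Splits with so many genes keep part of the difference between stages. For the interaction, 1 of 100 splits drawn gave as many as the real 161. The highest other was 160 and the next 149, so the real count led by only 1 gene. Splits that exchange the genotypes at 1 stage turn the shared effect of ESET loss into a difference between stages. Such splits are no fair reference for an interaction, and chance is not excluded by them. Among the 47 drawn splits that part every CD4SP pair of equal numbers, 1 gave as many and the highest other was 160 as well. With each array left out in turn the real count was 113 to 158. The split with 160 placed 1 of the 4 -/- preDP arrays and all 3 -/- CD4SP arrays in its first group, which nearly exchanges the genotypes in preDP.

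The Setdb1 signal was lower by 0.72 in -/- preDP but differed by -0.06 in -/- CD4SP, and the interaction of 0.65 ± 0.17 did not pass (adjusted p = 0.0641). At the lower 95% limit of the CD4SP difference (-0.33), undeleted cells would need a share of at least 47.3% in the -/- CD4SP samples. This takes the preDP fall of the signal as exact. That share allows falls of at most 2.12-fold, if undeleted cells resemble +/+ cells and deleted CD4SP cells show the preDP fall of the signal. Neither condition was measured. The error of the preDP fall was not counted, and a smaller preDP fall would lower the share and allow larger falls. Only under these conditions and with an exact preDP fall are undeleted cells argued against as the whole cause. There, 24 genes measured in both groups fell by more. Falls such as those of Klra16 and Klrd1 could also come from fewer NK receptor-bearing cells. A partial share is not excluded: genes raised in -/- preDP averaged 0.45 to 0.49 in -/- CD4SP. In -/- preDP, where they were picked, they averaged 0.88 to 0.95. Scaling or background correction is argued against, since the lowest CD4SP difference over 5 other normalizations was -0.072. It stays open that the probe may lie outside the deleted part of the gene, since the interaction of 0.65 cannot place it. A biological difference between the stages was not tested.

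The lower NK cell markers in -/- CD4SP (8 of 13, most of them receptor genes) were set against a technical and a cellular source. Over 5 other normalizations the fewest of these genes past the threshold was 5, short of the 6 named in advance, so a part played by scaling or background correction is not excluded. Yet lost calls were not always smaller falls: with the authors' normalized values, among those with the fewest, Klrd1 differed by -2.85 ± 1.00 SE (main value -2.15 ± 0.24) and Eomes by -3.70 ± 0.98 (-1.11 ± 0.15), so these calls ended because the spread grew. The list's median lay below 0 in all 5, from -2.85 to -0.26, so its size depends on the background treatment while its direction did not change. Of the 11 list genes that rise from preDP to CD4SP in +/+, 8 (72.7%) were lower and 0 higher in -/- CD4SP, while Nkg7, Fcer1g and Il2rb did not pass (0.57, 0.23 and -0.34). Without -/- CD4SP 03, 3 genes of the list rose beside 8 that fell. As 11 of 17 myeloid markers rose in the same setting, and Tyrobp and Fcer1g are in both lists, these rises do not decide on the share of NK receptor-bearing cells. A smaller share of NK receptor-bearing cells in the sorted population may account for the falls and is neither shown nor excluded, since lower expression per cell would give the same values. Several of the genes are at the background level in -/- CD4SP, where Klra7, Klrb1c and Klrk1 had means of 4.34, 4.26 and 4.27.

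In 18 of 184 combinations of a gene and a preDP group, 1 array stood apart from the other 3 by Dixon's ratio, where chance gives about 1 in 20. On +/+ preDP 04 these were Emid1 (ratio 0.928; log2 value 6.24 against 6.45 to 6.47), Slfn2 (0.913; 5.37 against 5.75 to 5.79), Klrd1 (0.937; 4.60 against 4.21 to 4.23), Dusp2 (0.875; 8.83 against 8.10 to 8.19), Dusp1 (0.922; 9.19 against 8.08 to 8.16) and Bcl2 (0.892; 5.86 against 5.48 to 5.52). On +/+ preDP 02 they were Siglech (0.867; 6.44 against 5.40 to 5.54), Tpx2 (0.852; 8.59 against 8.90 to 8.96), Brdt (0.974; 7.52 against 7.17), Xlr4a (0.869; 11.69 against 11.30 to 11.35), Tbp (0.894; 7.98 against 8.10 to 8.11) and Bid (0.861; 7.77 against 8.32 to 8.40). Bax stood apart on +/+ preDP 01 (0.920; 7.14 against 7.88 to 7.94), and Cxcr3 (0.842; 4.94 against 4.19 to 4.31) and Ctss (0.941; 4.47 against 4.59 to 4.60) on +/+ preDP 03. Fcrla (0.836; 8.03 against 8.80 to 8.96) and Scara3 (0.966; 5.69 against 5.11 to 5.13) stood apart on -/- preDP 04, and Actb (0.925; 13.47 against 13.20 to 13.22) on -/- preDP 02.

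A difference in the effect of ESET loss between CD4SP and preDP passed the interaction test in 161 genes. The genes reported here are given with CD4SP minus preDP values in log2. Among the genes named for preDP it was -1.87 for Fcrla, -3.13 for Il18r1, -1.66 for Fcgr2b, -1.81 for Rsph1 and -1.69 for Trim80. It was 1.08 for Kcnh3, 1.38 for Slc7a11, 1.14 for Wdr78, 1.00 for Scara3, 0.90 for Dusp4 and -1.25 for Cd53. Among those named for CD4SP it was 4.14 for Fstl4, 3.89 for Cited4, 3.26 for Itgb4, 1.59 for Grhl2, 1.07 for Snai3, 1.71 for Acoxl, 1.19 for Mbd1, 0.77 for Spo11 and 0.84 for Tnfrsf9. On the negative side it was -3.69 for Igfbp4, -2.88 for Klra16, -2.67 for Il4, -2.68 for Gpr83, -2.23 for Klrd1, -1.59 for Klra10, -1.66 for Klra7, -1.53 for Klrb1c and -1.52 for Nrn1. List members had -1.40 for Itgae, -1.17 for Eomes, -1.50 for Klra1, -1.23 for Hhex, -1.26 for Cxcr3 and -1.14 for Ccr8. Of the genes called in opposite directions, Amigo2 had -1.72, Fam110b 1.15 and Gpr183 -1.33. Slc7a11 and Scara3 were each detected on 1 of 3 +/+ CD4SP arrays. A fall could not be measured in CD4SP, so the positive values of these 2 genes restate their preDP falls.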

How the results depend on the processing

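The settings with the negative control signal added back, each probe tested on its own, preDP 01 and 03 averaged, preDP 03 of both genotypes left out and CD4SP 03 of both genotypes left out were chosen after seeing the data. Of 3206 values of named genes recomputed, 3008 kept their direction and their side of the threshold, 180 no longer passed, 13 newly passed and 5 changed sign. The cause was not tested, unless the setting itself removes samples.

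Without background correction and with signals floored at 1, 49 genes were lower in -/- preDP (main value 87), 71 lower in -/- CD4SP (160) and 40 had an interaction (161). With the authors' normalized values these were 49, 77 and 40. Of the main calls, 141 of 228 in preDP and 162 of 322 in CD4SP were kept without background correction, and 143 and 170 with the authors' values. With only the arrays compared, 102 genes were lower in CD4SP and 8 lower at both stages. With array weights Fcgr2b in CD4SP was 1.19. With preDP 01 and 03 averaged, which leaves fewer samples, 43 genes were lower in preDP, 107 had an interaction and 9 were lower at both stages. With preDP 03 of both genotypes left out these were 41, 104 and 7, and Mcm7 in preDP became 0.12. With CD4SP 03 of both genotypes left out Fcgr2b in CD4SP was 1.43. Actb in preDP became 0.0256 with the mean of its probes. A fold minimum of 2 left 41 higher and 10 lower in preDP, 54 and 31 in CD4SP, 76 interactions, and 1420 (+/+) and 1355 (-/-) changes with maturation. In postDP, an offset of 50 gave 43 genes at least 2-fold higher and 26 lower, no background correction 533 and 519, and the authors' values 530 and 515.

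With the replicate block 160 genes were lower in preDP, 297 higher and 270 lower in CD4SP, 278 had an interaction, 69 were higher and 29 lower at both stages, and Fcgr2b in CD4SP was 0.96 (adjusted p = 0.0396). It changed no other call of a named CD4SP gene than those of Fcgr2b, Cd160, Cd8b1, Lyz1, Siglech and Nusap1. In preDP equal numbers correlated with 0.218, 0.482, 0.208 and 0.0757, so not every pair was over 0.1: -/- 01, 02 and 04 correlated best with their own number and -/- 03 with +/+ 04 (0.321).

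With each array left out in turn, the counts ranged from 117 to 148 higher and from 57 to 91 lower in preDP, from 115 to 172 higher and from 113 to 155 lower in CD4SP, from 113 to 158 for the interaction, and from 4354 to 4804 (+/+) and 4261 to 4593 (-/-) with maturation. Setdb1 ranged from -0.79 to -0.66 in preDP and from -0.16 to 0.0672 in CD4SP, and Fcgr2b from 2.52 to 2.69 and from 0.47 to 1.44. Prf1 in preDP ranged from -0.59 to 0.16, with 0.07 without -/- preDP 03, and Mcm7 in preDP from -0.50 to 0.0613. Rasgrp1 lost its preDP call without 7 of the 8 arrays taken singly, Id3 and Morc3 without 6, Il2ra, Ly6a and Slfn2 without 5 and Ifi27 without 3.

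No block by BeadChip was run, since the sources used here do not give the chip, no interaction with only the arrays compared, and no block within stages for the change with maturation. Signal over background limits genes near the negative control level (78.9 to 88.2 in signal): their values depend most on the offset and the background correction. No scaling moved the median of all genes by more than 0.1.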

Other observations

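The test of neighbouring genes was prompted by pairs seen among the raised genes, and its counts were not seen before it was run.

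The probe for Iap, the symbol of the intracisternal A particles, a family of endogenous retroviruses, was chosen after its values were seen. The keyword search of the retrovirus-related list had not found it, so its description holds none of the keywords. What the probe reads was taken from the symbol and was not checked further. The probe's signal was among the bright ones of the array, with a mean log2 value of 11.88 in +/+ preDP and 12.79 in -/- preDP, and of 11.81 and 12.72 in CD4SP. It rose without ESET by 0.91 ± 0.12 in preDP (adjusted p = 0.000205, higher on 4 of 4 arrays) and by 0.91 ± 0.14 in CD4SP (adjusted p = 0.00074, higher on 3 of 3 arrays), with an interaction of 0.003 ± 0.188, and differed by 0.59 in postDP. It kept both calls in each alternative setting that was run. The array has 1 such probe, which may read several copies of the element, and under the authors' normalized values its differences were 0.91 and 0.93.

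Several genes raised without ESET stand next to one another along the chromosomes (gene order from the GRCm38.p6 table). Fcgr2b lies 2 places from Fcrla, Gpc2 (0.61 in preDP and 1.37 in CD4SP) 1 place from Stag3, Slc37a1 (0.79 in preDP) 1 place from Rsph1, Rims3 (1.15 and 1.25) 3 places from Cited4, and Cfap53 (0.97 in CD4SP) 1 place from Mbd1. These partners were picked after their values were seen. Of 253 genes raised at either stage with a known place, 66 had another raised gene within 5 places, against a mean of 32.4 in random sets of tested genes (permutation p = 0.0001, the smallest that 10000 sets can give). Probes of 1 gene family might read the same transcript, and symbols with the same first 3 letters were taken as 1 family. Without such pairs 57 remained (permutation p = 0.0011). This rule kept the pair of Fcrla and Fcgr2b. Lowered genes had 41 of 219 (permutation p = 0.0094), and 30 without family pairs (permutation p = 0.192).

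Chance and a flank of the altered Setdb1 allele are therefore argued against as the source of the raised neighbours. So are related probes, as far as similar symbols mark them. Of 63 genes tested within 50 places of Setdb1, 1 was called at either stage (1.59%, against 5.01% elsewhere, Fisher's exact one-sided p = 0.961). A candidate explanation is that silent regions opened without ESET hold more than 1 gene. Neighbours that share regulation for other reasons would give the same count, and this was not tested.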
